A study of Mus musculus with 4 samples.

How the data were processed

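RNA was measured by bulk sequencing in thymic epithelial cells of C57BL/6 mice. The 4 libraries are mTEC and cTEC from SCD1 knockout mice and from littermate controls (labelled WT), 1 library per group, made with the NEBNext Ultra RNA kit by a sequencing company. How many mice contributed to each library is not given in the sources used here.

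The authors deposited raw read counts per gene. Per the submitters' processing notes, reads were handled with CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3 on the mouse build mm10. The annotation release, strand setting and treatment of reads that map to several places are not given in the sources used here, and these settings affect genes with near-identical copies. The deposited table holds 54532 gene identifiers with symbols, positions and biotypes, and, per the file headers, a gene length in bases, which is of another (other) unit and was not used. The values were whole numbers with different totals per library, and no pair of columns was identical. The largest and smallest totals were 18151725 and 15740383 reads.

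Counts were scaled with the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 1.03 in both mTEC libraries, 0.971 in control cTEC and 0.966 in knockout cTEC. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Log2 ratios were taken on scaled counts with a prior count of 0.5 reads per library. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval, and each level in CPM (read counts scaled to library size, the field's standard depth unit) an exact 95% Poisson interval. Sequencing reads are not independent molecules, so intervals and floors cover counting error only. A floor of 3 counts corresponds to 0.176 CPM in control mTEC, 0.171 in knockout mTEC, 0.196 in control cTEC and 0.171 in knockout cTEC.

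No p-value was computed. Each group has 1 library, and the 1 residual degree of freedom of an additive model of genotype and population is a difference between populations rather than between libraries of a group, so that no test was taken from it. Genes were counted by a size rule: at least 50 reads summed over the 2 libraries compared, an absolute log2 ratio of at least 1 and a counting interval that excludes 0. The comparisons were knockout against control in mTEC and in cTEC, mTEC against cTEC in each genotype, the overlap of the genotype differences and their difference between populations. Overlaps were set beside the number expected from independent lists. Correlations are across genes and have no test.

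The named genes were chosen by a rule written before the data were examined, as were the 30 gene lists. Scd1 comes first. For each genotype comparison, the 10 higher and 10 lower protein-coding genes with the interval bound farthest from 0 are named, without predicted gene models and antigen receptor segments. Up to 5 genes per side are named for the shared difference and for the difference between populations. Marker list members are named for mTEC against cTEC, and up to 4 members with the largest ratios for each list. A single list member among those selected by this rule is not reported here.

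The lists cover the SCD family, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and PPAR targets, lipid uptake and LXR targets, the unfolded protein response, antioxidant response and ferroptosis, nuclear oxidative phosphorylation, MHC class II and class I presentation, interferon response, proliferation, thymocyte support and costimulation, markers of cTEC, mTEC, general TEC, tissue-restricted antigens, tuft cells and other mimetic cells, thymocytes, B cells, myeloid cells, fibroblasts, endothelium, erythroid cells and adipocytes, immediate early genes, ribosomal proteins, the mitochondrial genome and sex-linked genes. Each median log2 ratio over genes with at least 50 reads was placed among 10000 random lists matched on mean expression in 20 bins (seed 1), and given a 95% counting interval from 1000 Poisson resamplings. A random list falls outside the percentiles 2.5 to 97.5 in 5% of cases. In a simulated pair with some genes set to known ratios, 3.5% of lists drawn at random did so in mTEC and 8.0% in cTEC. Such lists were themselves random draws, so these shares do not test real lists. Genes of a real list can vary together, which random lists do not take into account. A further 7 lists were written after the first results were seen: second lists of thymocyte, endothelial and interferon genes, ATF4 targets with and without members of the lists above, liver secreted proteins and liver enzymes. Older symbols were matched for Ero1lb and Mucl2.

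To measure sequence sharing, the longest GENCODE release 21 mouse transcript of each gene was divided into 50-base windows, and a gene with 25% or more of its windows in another gene is described as having near-identical copies. Windows were matched on either strand. Genes that overlap at the same place in the genome were not left out, so they can also count as copies. Of the gene identifiers, 99.77% occur in that release. A copy was counted in a gene's family when they share at least 10 windows that make up at least 25% of the copy's own windows.

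The procedure was tested on simulated data with 20 unchanged pairs and with genes set to known ratios. The 95% intervals held the true ratio in 95.76% of cases for mTEC and 95.56% for cTEC. Other settings tried were DESeq2 1.42.0 size factors, library size alone, upper-quartile scaling, no minimum of reads, a minimum of 200 reads, a prior count of 5, thinning to the smallest library, protein-coding genes only, leaving out other cell type, erythroid, mitochondrial and immediate early genes, and thresholds of 1.5-fold and 4-fold. Leaving out genes with near-identical copies and leaving out the liver secreted proteins were added after the data were seen.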

Results

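Thymic epithelial cells build the niches in which T cells develop. Cortical cells (cTEC, sorted as Ly51+ UEA1−) drive early thymocyte development and positive selection, and medullary cells (mTEC, sorted as Ly51− UEA1+) express tissue-restricted antigens under the control of Aire. RNA of both populations was sequenced from C57BL/6 mice lacking SCD1, the stearoyl-CoA desaturase that makes oleic acid from stearic acid, and from littermate controls. The series holds 4 libraries, 1 for each combination of genotype and population, and the reads assigned to genes numbered 16467844 in control mTEC, 17051620 in knockout mTEC, 15740383 in control cTEC and 18151725 in knockout cTEC. There were no replicates, so no difference has a replicate check, the 95% intervals cover counting error only, and the comparisons are of these libraries rather than of the conditions. At least 10 reads were found for 19539 and 19654 genes in the control and knockout mTEC libraries and for 16839 and 17040 genes in the cTEC libraries. The Y-linked gene Ddx3y had 1577 to 1942 reads per library and the X-inactivation transcript Xist 17 to 25. The median log2 ratio of the sex-linked genes between genotypes was 0.02 in mTEC and 0.04 in cTEC.

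The first comparison asked whether the targeted gene was lower in the knockout libraries. Scd1 (ENSMUSG00000037071, mm10 chromosome 19, 44394451 to 44407709, minus strand) stood at 76.9 CPM (read counts scaled to library size) in control mTEC (95% interval 72.8 to 81.1) and at 15.8 in knockout mTEC (14.0 to 17.8), 4.85-fold lower. In cTEC it stood at 21.3 (19.0 to 23.7) in the control library and 4.16 (3.26 to 5.24) in the knockout library, 5.08-fold lower. The knockout libraries still held 278 and 73 Scd1 reads, and which part of the gene was deleted is not given in the sources used here. Scd2, the most abundant desaturase gene, was at 353 and 378 CPM in mTEC and at 443 and 497 in cTEC, with log2 ratios of 0.10 (0.05 to 0.15) and 0.17 (0.12 to 0.21). Scd3 was at 2.52 and 4.61 CPM in mTEC, a log2 ratio of 0.86 (0.32 to 1.44), and had 5 and 3 reads in cTEC. Scd4 was at 1.70 and 1.99 in mTEC and at 1.11 and 0.799 in cTEC. As a list, the 4 desaturase genes had a median log2 ratio of 0.16 in mTEC and a mean of −0.27, and the 2 measured in cTEC had a median of −1.09. With a minimum of 200 reads the mTEC median became −1.09, and without a minimum the cTEC median −0.64. Scd1 was the only member of this list that passed the size rule (at least 50 reads, at least 2-fold, interval excluding equality) between genotypes. Scd2 (44293676 to 44306864), Scd3 (44203288 to 44244016) and Scd4 (44333092 to 44346743) lie beside Scd1 on the plus strand of chromosome 19.

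**Figure D1:**
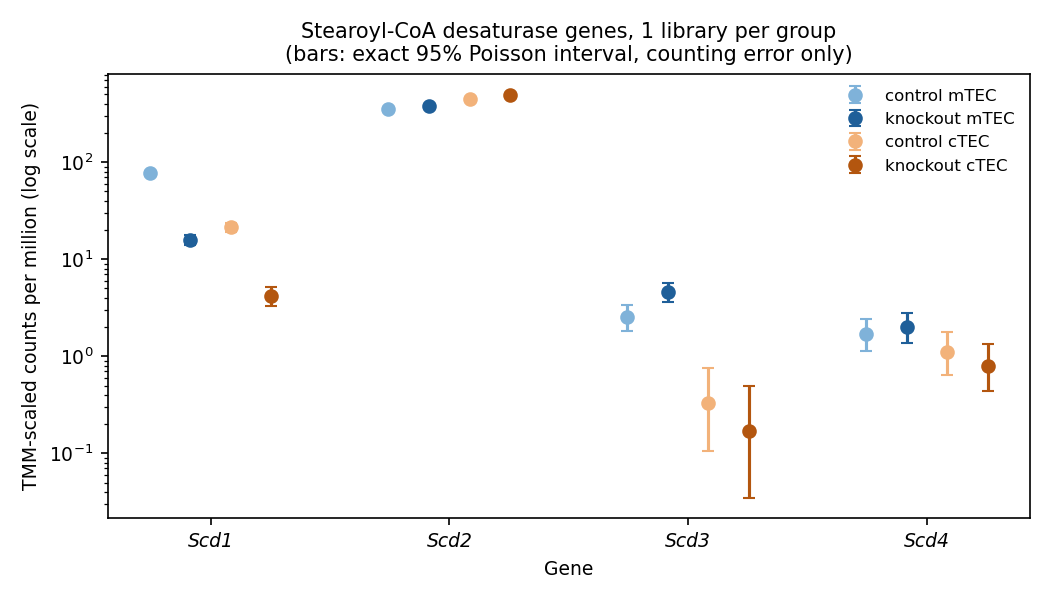
TMM-scaled CPM of the 4 stearoyl-CoA desaturase genes in each library on a log axis, with exact 95% Poisson intervals for counting error. Scd1 stood at 76.9 against 15.8 in mTEC and at 21.3 against 4.16 in cTEC, while Scd2 lay between 353 and 497 in all 4 libraries.

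In mTEC, the genotype comparison asked which transcripts of UEA1+ cells differed without SCD1. By the size rule, 83 genes were higher and 71 lower in the knockout library, of 16466 tested, and with a minimum of 200 reads 10 and 9. Among the genes named by the rule, those with the interval bound farthest from 0 were Ccl19 on the lower side and Srp54b on the higher side. Ccl19, a chemokine that attracts CCR7-bearing thymocytes to the medulla, had 264 control and 10 knockout reads (log2 ratio −4.70, −5.84 to −3.87), and Srp54b, a signal recognition particle subunit, had 31 and 177 (2.45, 1.91 to 3.07). Genes of cholesterol synthesis, thymic tuft cells and the cortical program were slightly higher as groups, and interferon response genes slightly lower. Markers of thymocytes and endothelium were also higher in this knockout library, with list medians of 0.29 and 0.55, although a second endothelial list had a median of 0.07.

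Ccl19 (ENSMUSG00000071005, chromosome 4, 42754525 to 42756577), Srp54b (ENSMUSG00000112449, chromosome 12, 55155104 to 55189573) and Sumo2 (ENSMUSG00000020738, chromosome 11, 115523102 to 115536276) share sequence with near-identical copies elsewhere in the genome. Of their 50-base windows, 59.1%, 99.8% and 30.2% occur in another gene. The 4 copies of Ccl19 together had 655 control and 1001 knockout reads, so that the family as a whole had 919 and 1011. Sumo2, a ubiquitin-like modifier, had 498 and 1733 reads, while its copies had 1110 and 517. The copies of Srp54b had 341 reads in each library, and its family 372 and 518. Tmem254c, whose windows all occur in other genes, was 6.59-fold lower, Snx22 3.09-fold lower and Rnf26 2.43-fold lower. Of the 154 genes passing in mTEC, 36 had such copies (23.4%, against 9.70% of the genes tested).

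Among named genes with few or no shared windows, Cldn5, an endothelial tight junction gene (10 and 53 reads), was 4.95-fold higher in knockout mTEC and stood with the endothelial list. The enamel protein gene Ambn (7 and 44 reads) was 5.76-fold higher, the pancreatic granule gene Sycn 3.93-fold and BC051019 4.34-fold. Pianp was 2.91-fold higher, the kinase gene Dclk3 2.35-fold and the potassium channel gene Kcnh8 had 28 and 73 reads (1.32, 0.69 to 2.02). Ndufa12, a complex I subunit with 17.2% of its windows shared, was 2.25-fold higher (326 and 758 reads). In the cTEC pair Ndufa12 lay the other way (691 and 433 reads, log2 ratio −0.87, −1.05 to −0.70). In the other direction, Armc2 was 3.26-fold lower, Dbndd1 3.09-fold, the retinol and alcohol dehydrogenase gene Adh7 2.59-fold, the plasma protein gene Ahsg 2.18-fold and Fam20a 2.04-fold. Each of these has an interval that excludes equal expression, with 50 or more reads over the pair.

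Of the lipid lists fixed before the data were examined, cholesterol synthesis had the clearest shift in mTEC. Its median log2 ratio was 0.14 (0.09 to 0.19, percentile 99.98 among 10000 random lists of matched expression), 19 of 22 measured genes were above 0, and none passed the size rule. Insig1 stood at 0.43 (0.25 to 0.62), Hmgcs1 at 0.33 (0.22 to 0.44) and Cyp51 at 0.26 (0.15 to 0.38). Fatty acid oxidation and PPAR targets had a median of 0.08 (0.01 to 0.11, percentile 99.12), with Acaa2 at 0.35, Ehhadh at 0.32 and Angptl4 at −0.27. Fatty acid synthesis genes had a median of 0.04 (−0.01 to 0.09), and Srebf1, the transcription factor gene of that pathway, stood at 0.26 (0.19 to 0.34). Lipid uptake and LXR targets had a median of 0.03, with Cd36 at 0.87 (0.30 to 1.48) and Fabp4 at 0.40 (0.32 to 0.47). No gene of these 4 lists passed the size rule in mTEC. Nuclear oxidative phosphorylation genes had a median of 0.05 (percentile 98.75), with 18 of 20 above 0, the unfolded protein response genes 0.03 and the antioxidant and ferroptosis genes 0.03.

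Epithelial programs in mTEC moved unevenly between genotypes. The cTEC marker list had a median of 0.17 (0.15 to 0.28, percentile 100) in the mTEC pair, with 11 of 12 genes above 0, among them the thymoproteasome gene Psmb11 (706 and 1026 reads) and Prss16 (6191 and 8940 reads). The thymic tuft cell list had a median of 0.37 (0.18 to 0.46, percentile 100), with 9 of 10 genes above 0. Il25, the tuft cell cytokine gene, passed the size rule (19 and 53 reads, 1.41, 0.66 to 2.27), and Gnat3 stood at 0.50 and Plcb2 at 0.43. The mTEC markers had a median of −0.03 and a mean of −0.26, with Ccl19 the only member past the rule, Ccl22 at 0.32 and Trp63 at −0.20. Aire had 21598 and 22186 reads. Tissue-restricted antigens had a median of 0.11 (−0.04 to 0.19), with Sst at 0.52 and Chga, a neuroendocrine granule gene, at −0.48 (−0.51 to −0.45). The other mimetic cell genes had a median of 0.01 and general TEC markers of −0.0021, and both these signs depend on the scaling.

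Immune lists in the mTEC pair were led by the interferon response. Its median was −0.08 (−0.11 to −0.05, percentile 0.13), with 15 of 16 genes below 0 and Mx1 at −0.40 (−0.53 to −0.26). MHC class II genes had a median of 0.06 (0.05 to 0.10) and MHC class I genes of −0.0024, with a mean of 0.0007 and a sign that depends on the scaling. Thymocyte support and costimulation genes had a median of 0.03, or 0.087 without genes with near-identical copies, and a mean of −0.15. Ccl19 was their only member past the rule, and Tnfsf4 had 26 and 54 reads (log2 interval 0.31 to 1.75). Proliferation genes had a median of −0.05.

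Among other cell types, the thymocyte list had a median of 0.29 in mTEC (0.21 to 0.41, percentile 100), with Themis at 0.75 and Cd3g at 0.53, and the endothelial list 0.55 (0.26 to 0.77, percentile 99.96), with Tek at 0.75 and Pecam1 at 0.48. With a minimum of 200 reads the endothelial median was 0.22, and a second endothelial list had a median of 0.07 (−0.13 to 0.21). Myeloid and dendritic cell genes had a median of 0.20 (0.02 to 0.24), B cell genes 0.31 (0.02 to 0.46), fibroblast and pericyte genes 0.04, erythroid genes 0.16 and adipocyte genes −0.03 with a mean of 0.03. Immediate early genes had a median of 0.03, ribosomal protein genes 0.02 and the mitochondrial genome 0.03. In 20 simulated pairs without any true difference, counting error alone gave a median of 13 passing genes, against the 154 found here. Of 28 lists, all but the SCD family and the sex-linked genes, 8 lay above and 1 below the middle 95% of random lists, against 1.4 expected outside it. In a simulated mTEC pair with some genes set to known ratios, 3.5% of random lists lay outside.

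In cTEC, the same question was asked of the Ly51+ cells. Here 71 genes were higher and 100 lower in the knockout library, of 14445 tested, and with a minimum of 200 reads 7 and 13. The largest differences included plasma protein genes. Alb, the serum albumin gene, had 526 control and 80 knockout reads (−2.91, −3.27 to −2.57), and Serpina1a had 50 and 0, at least 19.12-fold lower against a floor of 3 counts. Trib3, a pseudokinase gene of the integrated stress response, had 45 and 195 reads (1.91, 1.44 to 2.42). The cTEC marker list was higher and the interferon response list lower in the knockout library, by medians of 0.32 and −0.22. Thymocyte and endothelial markers were higher, by medians of 0.38 and 0.71, although a second endothelial list had a median of 0.11.

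Alb (ENSMUSG00000029368) lies on chromosome 5 at 90460897 to 90476602, and Ahsg (ENSMUSG00000022868), the fetuin gene, on chromosome 16 at 22891277 to 22899449. Ahsg had 83 and 2 reads in cTEC, a log2 ratio of −5.24 (−8.64 to −3.67). The antiprotease genes Serpina1b (76 and 4 reads) and Serpina3k (46 and 9 reads) were 19.3-fold and 5.59-fold lower. The inner ear gene Otog (289 and 41 reads) was 7.99-fold lower and the airway secretoglobin gene Scgb3a2 5.35-fold lower. Ccl21c, a CCR7 ligand gene placed on an unassembled scaffold where copies were not measured, was 5.24-fold lower (354 and 77 reads). The Ccl21a gene model, whose copies were not measured either, had 1843 and 3447 reads in the same pair. Whether reads were exchanged between Ccl21a and Ccl21c was not tested. Srp54b was 5.49-fold lower in this pair (141 and 29 reads). Serpina1a shares 67.4% of its windows with other genes and Serpina1b 35.8%.

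Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032) was 3.75-fold higher in knockout cTEC. Aldh1l2, a mitochondrial folate enzyme gene, was 3.23-fold higher (21 and 79 reads) and Chac2, which degrades glutathione, 2.43-fold. Gapdh (ENSMUSG00000057666, chromosome 6, 125161715 to 125166467) had 778 and 2948 reads (1.72, 1.61 to 1.84), and 27.8% of its windows occur in other genes. Its copies had 381 and 404 reads, so the whole family also stood higher (1159 and 3352 reads). Sarnp (42.0% of windows shared) was 2.47-fold higher, but its family had 716 and 949 reads. Sdhaf1 (69.0% shared) was 2.52-fold higher. Tox3 was 2.34-fold higher, Ercc6l, a mitotic helicase gene, 3.12-fold, the ubiquitin ligase gene Rnf125 2.32-fold and Rgs1, a G protein regulator of lymphocytes, 2.02-fold. Of the 171 genes passing in cTEC, 50 had near-identical copies (29.2%, against 10.4% of the genes tested).

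**Figure D2:**
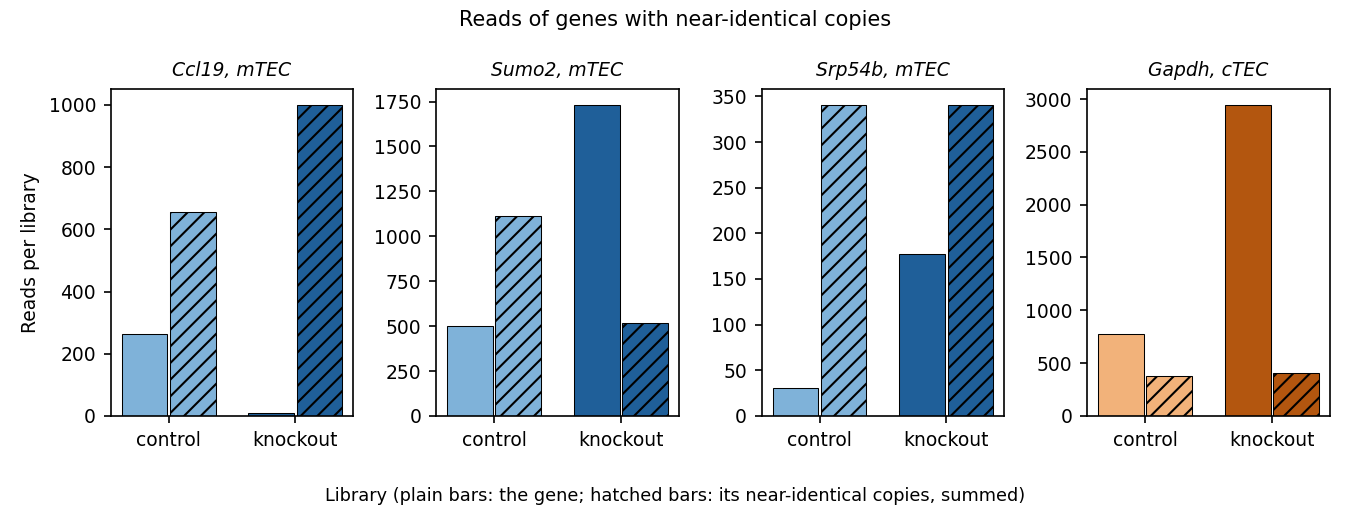
Reads per library of 4 named genes (plain bars) and of their near-identical copies summed (hatched bars), in the control and knockout libraries, on axes that start at 0. In mTEC, Ccl19 had 264 and 10 reads against 655 and 1001 for its copies, and in cTEC Gapdh had 778 and 2948 reads against 381 and 404.

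The 4 lipid pathway lists in the cTEC pair had medians within the range of random lists, and none of their genes passed the size rule. Cholesterol synthesis genes had a median of 0.09 (0.04 to 0.14, percentile 97.15), 18 of 22 above 0, with Sc5d at 0.22 and Ebp at −0.24. Fatty acid synthesis genes had a median of 0.03 and a mean of −0.0037, although Fasn, the fatty acid synthase gene, stood at 0.41 (0.37 to 0.46) and Thrsp at −0.71 (−1.30 to −0.14). Fatty acid oxidation and PPAR targets had a median of −0.02, with Ehhadh at 0.46 (0.26 to 0.66) and Angptl4 at −0.37 (−0.55 to −0.18). Lipid uptake and LXR targets had a median of 0.03, with Fabp4 at 0.47, Lpl at 0.35 and Apoe at −0.26. The unfolded protein response list had a median of 0.05, with Trib3 past the size rule and Asns, which makes asparagine, at 0.72 (0.55 to 0.90). Antioxidant and ferroptosis genes had a median of −0.07 and nuclear oxidative phosphorylation genes of 0.05.

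The cTEC markers had a median of 0.32 (0.28 to 0.33, percentile 100) in the cTEC pair, with Cd83 at 0.53 (3888 and 6436 reads), Tbata at 0.39 and Dll4, the Notch ligand gene, at 0.34, and Il7 the only member below 0. General TEC markers had a median of 0.09 (0.04 to 0.12), with Foxn1, the regulator of epithelial identity, at 0.27. The mTEC markers had a median of −0.16 (−0.18 to −0.01), with Fezf2 at −0.33, Tnfrsf11a at −0.44 and a Ccl21a gene model at 0.70. Tissue-restricted antigens had a median of −0.25 over 5 genes, with the plasma protein gene Ttr past the rule (40 and 13 reads, −1.78). Tuft cell genes had a median of −0.06, with Ltc4s past the rule (32 and 18 reads, −1.01), and other mimetic genes −0.06 (Sbsn at −0.91).

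Interferon response genes in cTEC had a median of −0.22 (−0.26 to −0.19), below all 10000 random lists, with Mx1 at −0.42 (−0.56 to −0.29), Isg15 at −0.31 and Irf7 at −0.28. Immediate early genes, a sign of handling, were lower in the same library, with a median of −0.13 (−0.14 to −0.12), or −0.070 without genes with near-identical copies. MHC class II genes had a median of 0.06 and MHC class I genes of −0.03 with a mean of 0.0003. Proliferation genes had a median of 0.15 (0.08 to 0.26, percentile 99.4), with Aurkb at 0.66 and Ccnb1 at −0.97, and thymocyte support genes 0.11 (0.03 to 0.16), with Pdcd1lg2 at −0.61. The median of the thymocyte support genes turned to −0.007 without a minimum of reads.

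Thymocyte markers, which were higher beside these, had a median of 0.38 in cTEC (0.30 to 0.46, percentile 100), all 14 above 0, with Cd5 at 0.90 and Dntt at 0.48. Endothelial markers had a median of 0.71 (0.34 to 1.02) over 5 genes, with Cdh5 past the size rule (17 and 53 reads, 1.42) and Pecam1 at 0.94, while the second endothelial list had a median of 0.11 (−0.15 to 0.41). Myeloid and dendritic cell genes had a median of 0.27 (0.12 to 0.39), with C1qc at 0.79, fibroblast and pericyte genes 0.04 (−0.15 to 0.20) and B cell genes −0.05 over 2 genes. Erythroid and adipocyte genes had too few reads to measure. The mitochondrial genome had a median of 0.25 (0.19 to 0.25) and ribosomal protein genes of 0.03. Counting error alone gave a median of 9.5 passing genes in simulated cTEC pairs. Of 26 lists, 8 lay above and 4 below the middle 95% of random lists, against 1.3 expected outside it at the nominal 5%. This tally leaves out the sex-linked genes and the SCD family, which was at percentile 0.09. In a simulated cTEC pair with some genes set to known ratios, 8.0% of random lists lay outside.

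**Figure D3:**
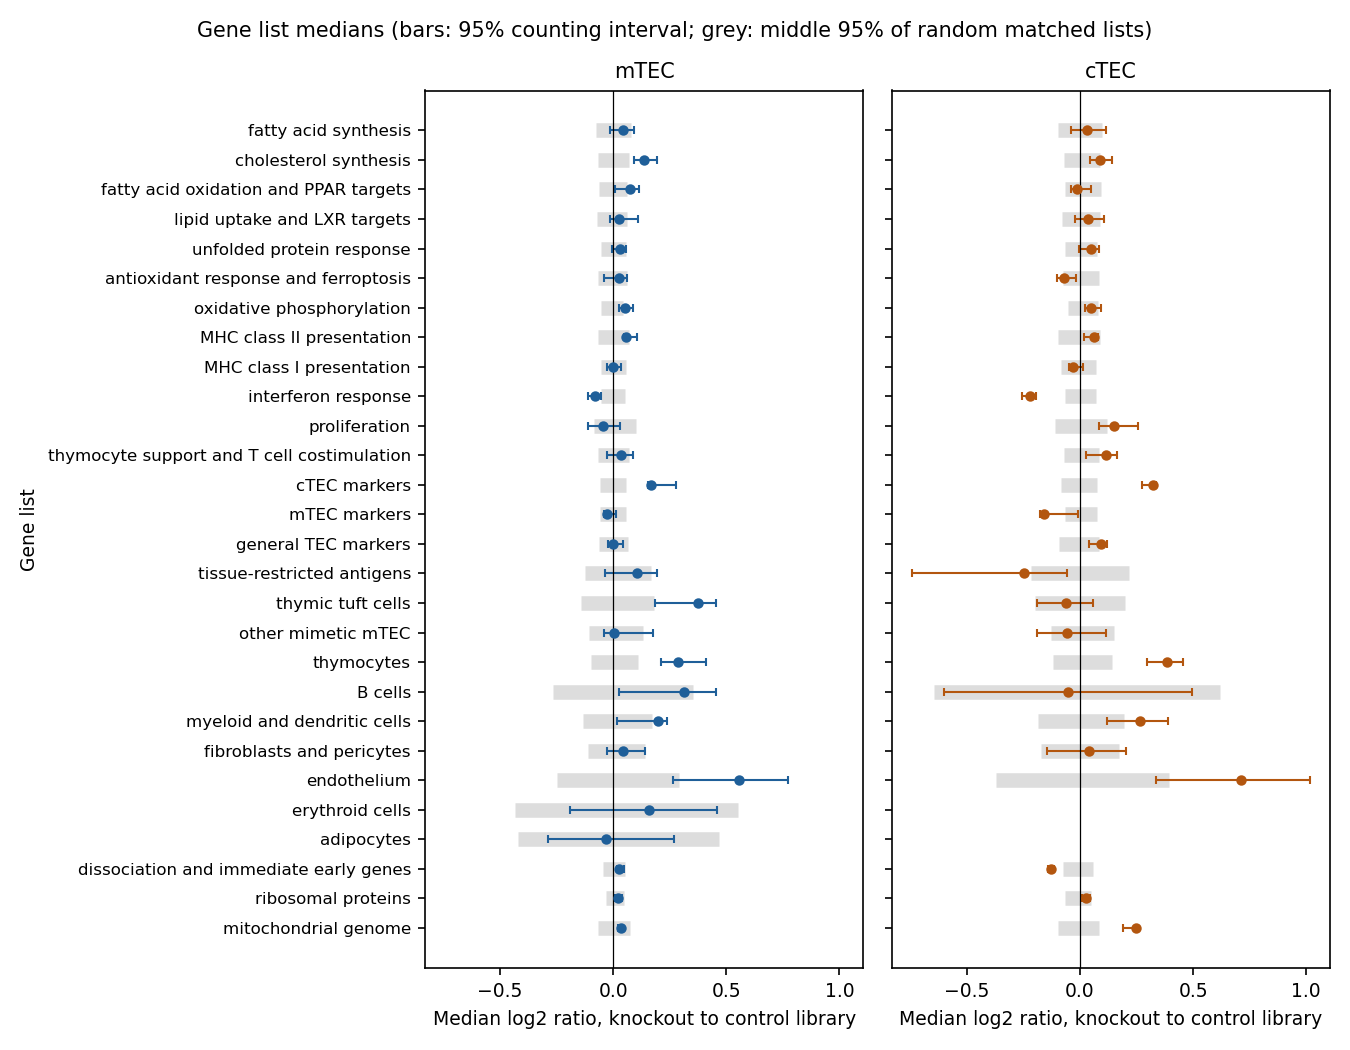
Median log2 ratio of knockout to control library for each gene list in mTEC and cTEC, with 95% counting intervals as bars and the middle 95% of random lists of matched expression in grey. The cTEC markers (0.17 and 0.32) and thymocyte markers (0.29 and 0.38) lie above the grey range in both populations, and the interferon response (−0.08 and −0.22) lies below it.

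The genotype differences shared by both populations were few. Scd1, Ahsg, Tmem254c and Wnt2, a growth factor gene, were lower in both knockout libraries, and Mmrn2, an extracellular matrix gene of endothelium, was higher in both (24 and 51 reads in mTEC, 22 and 53 in cTEC). Wnt2 stood at −1.06 (−2.01 to −0.21) in mTEC and −1.14 (−2.04 to −0.32) in cTEC. Of 13953 genes tested in both, 3 were higher in both against 0.116 expected from independent lists, 5 were lower in both against 0.202 expected, and 6 lay in opposite directions. No expected number was computed for opposite directions, so these counts do not show that a shared direction was favoured. With a minimum of 200 reads 0 were higher and 2 lower in both, and with a prior count of 5 none was higher in both. The other members, named here after their values were seen, were Gm9826 (1.06 and 1.75) and Rps25-ps1 (1.02 and 1.99) among the higher and Gm13304 (−1.19 and −1.58) among the lower, all with near-identical copies. Across genes, which are not independent replicates, the log2 ratios of mTEC and cTEC correlated with r = 0.0811 and rho = 0.109, with r = 0.0089 without a minimum of reads, and with r = 0.216 among the 5962 genes with at least 1000 reads in each pair.

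**Figure D4:**
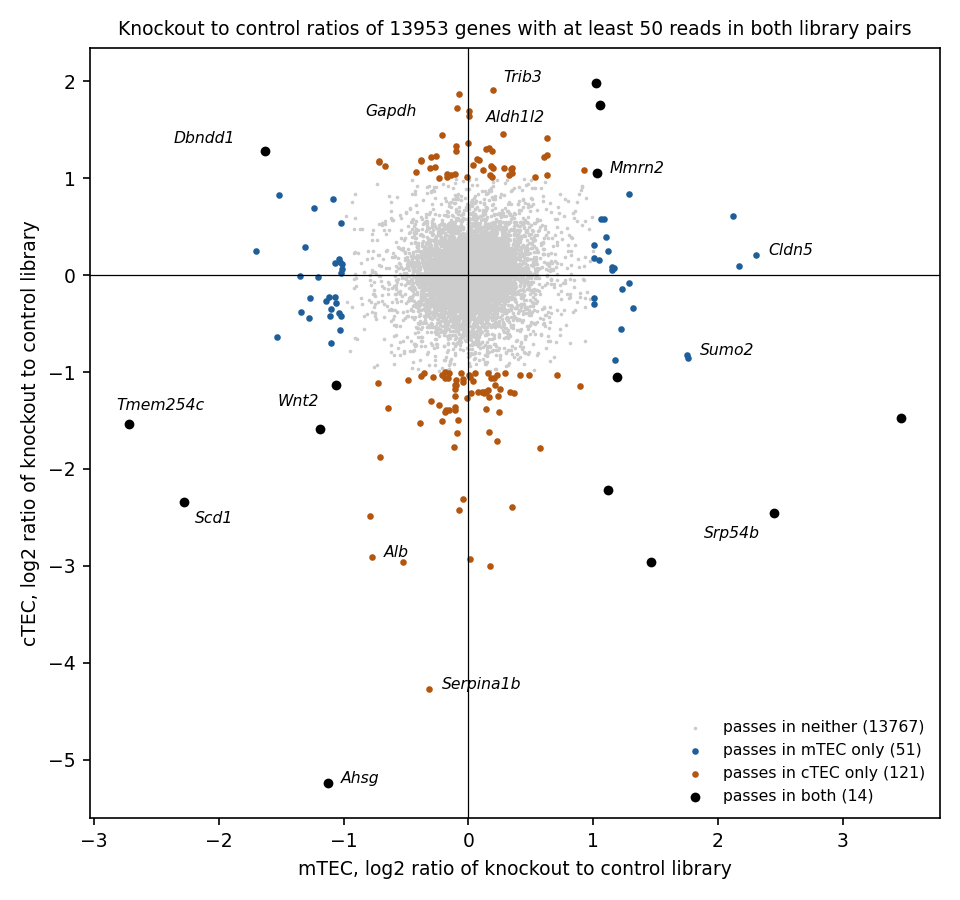
Log2 ratio of knockout to control library in mTEC (horizontal axis) and cTEC (vertical axis) for 13953 genes, coloured by whether they passed the size rule in neither, one or both populations. Scd1 lies at −2.28 and −2.34, while Srp54b lies at 2.45 and −2.46.

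Where the genotype ratio differed between populations, plasma protein genes and genes with near-identical copies were among the largest. The ratio in mTEC exceeded that in cTEC by 4.91 on the log2 scale for Srp54b, 4.12 for Ahsg, 3.96 for Serpina1b, 3.17 for Otog and 2.74 for Ccl21c. The ratio in cTEC exceeded that in mTEC for Dbndd1 (difference −2.91), Ppp1r3f (−1.90, with 54.8% of its windows shared), Pde8b (−1.87), Gapdh (−1.82) and Trib3 (−1.71). In total 114 genes had a ratio at least 2-fold larger in mTEC and 69 in cTEC with intervals that did not overlap. The difference itself has no test without replicates.

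The comparison of mTEC with cTEC described the populations in each genotype. In control libraries, Aire was 33.7-fold higher in mTEC, Fezf2 6.56-fold, Spib 15.2-fold and Cd80 8.55-fold, whereas Prss16 was 15.5-fold lower, Psmb11 13.4-fold and Cxcl12 10.5-fold. The mTEC markers had a median log2 ratio of 2.33 in controls and 2.17 in knockouts, and the cTEC markers −2.70 and −2.74, with 11 of 12 passing in each genotype. Scd1 was 3.61-fold higher in control mTEC than in control cTEC (1.85, 1.68 to 2.03) and 3.78-fold in knockouts.

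Tissue-restricted antigens had a median of 3.74 in controls and 3.53 in knockouts, with the casein gene Csn2 at 4.12 and 4.22. Proliferation genes stood higher in mTEC (1.54 and 1.07), as did other mimetic genes (2.13 and 2.36), thymocyte support genes (0.91 and 0.79) and the unfolded protein response (0.52 and 0.47). Tuft cell genes had medians of 0.66 and 1.07, within the range of random lists in both genotypes (percentiles 94.4 and 97.47). Fatty acid synthesis genes had medians of 0.11 and 0.16, within the range of random lists in both genotypes (percentiles 92.1 and 96.1). The SCD family had a median of 0.76 over 2 measured genes in controls, also within that range (percentile 92.2), and 1.92 over 3 in knockouts (percentile 98.0). Scd1 (1.85 and 1.92) and Scd2 (−0.33 and −0.39) were measured in both, so the higher median came with the added Scd3. Fatty acid oxidation and PPAR targets had medians of −0.53 and −0.53, lipid uptake and LXR targets −0.54 and −0.50, and cholesterol synthesis −0.39 and −0.25 (percentiles 2.67 and 23.6, within the range of random lists). Within fatty acid synthesis, Acacb stood at 4.40 and 4.68, Fasn at −1.42 and −1.79 and Srebf1 at −1.70 and −1.63, and Fabp4 of the lipid uptake list was higher in mTEC (3.31 and 3.23). Interferon response genes had medians of −0.48 and −0.36 (percentiles 1.86 and 10.3, the latter within the range of random lists). Thymocyte markers had medians of −0.50 and −0.55, while myeloid genes (1.23 and 1.12) were higher in mTEC. B cell genes had medians of 3.35 over 5 genes in controls and 2.02 over 6 in knockouts, the latter within the range of random lists (percentile 89.2). As the sets of genes differ, these 2 medians do not show a lower ratio in knockouts.

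Counts past the size rule were 2991 higher and 1341 lower of 15747 genes in controls and 3162 and 1430 of 15962 in knockouts. Both genotypes shared 2638 higher and 1039 lower genes, against 548 and 116 expected from independent lists, and 8 genes lay in opposite directions. Across 15509 genes the ratios correlated with r = 0.942 and rho = 0.917.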

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

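The tests of copy reads, of mTEC carry-over, of liver enzymes and of thymocyte against fibroblast medians were chosen only after the results they bear on were seen.

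Passing genes whose ratio was above 1 on the log2 scale in one population and below −1 in the other were singled out because the only library pair of each population moved the opposite way; the difference was not tested. Ccl19-ps3, a pseudogene, stood at 3.47 in mTEC and −1.48 in cTEC, and the predicted gene Gm10705 at 1.12 and −2.22. Srp54b stood at 2.45 and −2.46, and Eif3j2, a translation initiation factor gene, at 1.19 and −1.05. In the order named, these genes share 100%, 85.4%, 99.8% and 91.8% of their windows with other genes. Ccl19-ps3 belongs to the family of Ccl19, which as a whole had 919 control and 1011 knockout reads in mTEC. The immunoglobulin constant gene Ighg1 stood at 1.46 and −2.96. Dbndd1 was the only one lower in mTEC, at −1.63 against 1.28 in cTEC.

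Genes with near-identical copies made up 23.4% of the passing genes in mTEC and 29.2% in cTEC, against 9.70% and 10.4% of the genes tested. Genes that overlap at the same place in the genome can count as copies in these shares. In mTEC, the summed reads of the copies moved opposite to the gene in 56.5% of the 23 genes whose copies had at least 50 reads (34.5 to 76.8) and in 9 of the 13 whose copies' own interval excludes 0. In cTEC the share was 47.1% of 34 genes (29.8 to 64.9) and 7 of 13. Reads exchanged between copies may account for such differences, as for Ccl19, whose copies had 655 and 1001 reads. In 10 and 21 of these genes the copies' own interval includes 0, so that the copies' reads alone do not tell a true difference from an exchange. Genes of the same family, such as Ccl19, Ccl19-ps3 and Gm2564 in mTEC, were counted separately, so the shares do not come from independent genes. The intervals of the shares do not take this into account. Gene and copies summed were still at least 2-fold apart for 2 genes in mTEC and 9 in cTEC, such as Gapdh in cTEC (1159 and 3352 reads). An exchange among the counted copies alone would not give these differences, but the copies counted can leave out a related gene. Gm10241, among those in mTEC, was counted without Sumo2 (1110 and 517 reads). The family counted from Sumo2 had 1608 and 2250 reads, a log2 ratio of 0.441. Among those in cTEC, Serpina1a, Serpina1b and Serpina1e are of the same family. An effect of genotype on single copies was not tested and stays open.

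Plasma protein genes were lower in the knockout cTEC library: the list of liver secreted proteins, written after the values were seen, had a median of −1.35 (−1.66 to −1.09) over 20 genes, also with Serpina1a at its floor, and 25 of its 28 genes were also measured in mTEC. The list holds genes that prompted it, such as Ahsg and Serpina1a, so its median partly restates their values. Fewer mTEC of average composition carried over by the UEA1 gate is argued against, since 15 genes at least 32-fold higher in mTEC had a median of −0.161 (−0.473 to 0.133). Control cTEC also held 91.48 Alb reads per 100 Aire reads against 2.93 in control mTEC. These values do not cover carry-over of a subset of mTEC. Liver RNA in the control library, where Alb had 526 reads, may be a source that the Ly51 gate should remove, but 13 liver enzymes had a median of −0.228 (−0.419 to −0.095), and their expression in cTEC itself would hide a small share, so it cannot be told apart from lower expression in the knockout cells. The genotype, a group of the design, stays open as an untested explanation.

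Thymocyte and endothelial markers were higher in both knockout libraries. A lower share of epithelial cells would raise all other cell types alike. The thymocyte medians exceeded those of fibroblasts by at least 0.241 with intervals that did not overlap. Myeloid medians (0.20 in mTEC, 0.27 in cTEC) and B cell genes in mTEC (0.31) were also above 0. B cell genes in cTEC (−0.05) and adipocyte genes in mTEC (−0.03) were not. Fibroblast and pericyte genes differed between populations, such as Rgs5 (5706 reads in control mTEC, 643 in control cTEC). The fibroblast comparison thus cannot decide on the epithelial share. More thymocyte RNA is consistent with a second list of 16 thymocyte genes, whose medians were 0.274 in mTEC and 0.37 in cTEC, with Tcf7 at 1535 and 2488 reads in cTEC. For endothelium the second list had medians of 0.074 (−0.13 to 0.21) and 0.11, too imprecise to decide. Whether the extra RNA came with the sort on Ly51 and UEA1 or with the genotype was not tested.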

How the results depend on the processing

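The settings without genes with near-identical copies and without liver secreted proteins were chosen only after the data were seen; the other 11 were planned. Libraries were not paired by replicate, because each group has a single library and the labels do not say which libraries come from the same mice. A model with population as the block is another fit and was left out by choice, since its 1 residual degree of freedom is a difference between populations. An edgeR test was planned only in case the table held replicate columns. It holds none, so no such test was run.

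Over all settings, 133 counts and correlations stayed close to the reported values (counts within 1.5 times), 20 counts were larger, 34 smaller and 2 correlations moved. Of the list medians 583 stayed within their counting intervals, 14 moved and 1 reversed, and of the named gene ratios 708 stayed and 1 moved. All 154 passing mTEC genes and 167 of the 171 passing cTEC genes also passed with DESeq2 size factors, and 112 and 146 after thinning to the smallest library. The median of all genes shifted by less than 0.1 under each scaling.

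Without a minimum of reads, 519 genes were higher and 473 lower in mTEC and 496 and 684 in cTEC, with 5786 higher in mTEC against cTEC in controls and 6131 in knockouts, 33 and 31 shared, r = 0.0089, and 285 and 158 differing between populations. The SCD family in cTEC stood at −0.64 and thymocyte support in cTEC reversed to −0.007. With more genes admitted, counts grow by construction. With at least 200 reads, the counts were 10 and 9 in mTEC, 7 and 13 in cTEC, 1416 higher in controls and 1508 in knockouts, 0 and 2 shared, r = 0.14, and 19 and 12 differing. The SCD family in mTEC then stood at −1.09 and endothelium in mTEC at 0.22, since fewer genes were measured.

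A threshold of 1.5-fold gave 351 and 243 in mTEC, 311 and 365 in cTEC, 3010 lower in controls and 3155 in knockouts, 21 and 17 shared, and 240 and 174 differing. At 4-fold the counts were 9 and 8, 3 and 19, 1750 and 302 in controls, 1926 and 278 in knockouts, 0 and 1 shared, and 21 and 2 differing. A prior count of 5 gave 49 and 43 in mTEC, 42 and 63 in cTEC and 0 shared higher. Thinning left 1 shared higher gene. Protein-coding genes alone gave 43 lower in mTEC, 46 higher in cTEC and 1 shared higher. Counts at the 1.5-fold and 4-fold thresholds and among protein-coding genes change by construction; for the prior count and thinning the cause was not tested.

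With upper-quartile scaling, MHC class II moved to 0.045 in mTEC and 0.078 in cTEC, immediate early genes to 0.0125 and −0.11, cTEC markers in cTEC to 0.34, ribosomal proteins in cTEC to 0.043 and the mitochondrial genome in cTEC to 0.26; the cause was not tested. Without genes with near-identical copies, 47 genes were higher in cTEC, 1 and 3 were shared, thymocyte support in mTEC stood at 0.087, the mitochondrial genome at 0.0465 in mTEC and 0.256 in cTEC, and immediate early genes in cTEC at −0.070, from fewer genes.

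Depth limits what the size rule sees. Of the 154 and 171 passing genes, 19 and 20 passed with at least 200 reads over the pair. Simulated 4-fold differences were recovered at 100% in mTEC and cTEC, and 2-fold differences, which lie on the threshold itself, at 58.9% and 43.6%. For genes near the minimum of 50 reads the counting interval spans more than a 2-fold difference.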

Other observations

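The lists of liver proteins and the examination of immunoglobulin segments and of the genes around Scd1, and the ATF4 test without members of other lists, were chosen only after values were seen; the second interferon list was written before its own values were seen.

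Immunoglobulin segments varied between libraries. Together they had 5616 reads in control mTEC, 7223 in knockout mTEC, 4229 in control cTEC and 4319 in knockout cTEC. Single segments were far apart: Igkv12-44 had 8 and 348 reads in control and knockout mTEC, Ighv1-53 14 and 308 and Ighg2b 380 and 1328, while Igkv4-68 had 98 and 20 and Igkv4-59 0 and 87 in cTEC. Of 26 segments tested in mTEC, 6 were higher and 7 lower in the knockout library, and of 17 in cTEC, 1 was higher and 5 lower.

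Genes within 5 megabases of Scd1 did not pass the size rule: 0 of 119 other genes in mTEC and 0 of 96 in cTEC, with medians of 0.0012 and −0.0015 and ranges of −0.68 to 0.86 and −0.52 to 0.84. Liver secreted proteins, by contrast, were lower in mTEC as well, with a median of −0.13 (−0.26 to −0.02) over 25 genes, of which Vtn, Ahsg and Apoh passed. Of this list, Ttr and Fgb also stand in the list of tissue-restricted antigens. Liver enzymes with at least 50 reads had a median of 0.10 in mTEC and −0.17 in cTEC.

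Interferon response genes were lower in both knockout libraries, and a lower interferon response with the genotype is a candidate explanation. A second list of 25 interferon genes had medians of −0.092 in mTEC and −0.096 in cTEC (percentiles 0.01 and 0.06), with 22 of 25 genes below 0 in each, among them Oas2 and Rtp4. The shift is well under 2-fold, no gene passed the size rule, and handling differences between single libraries may give the same.

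Trib3, Aldh1l2 and Chac2 were higher in knockout cTEC, and a higher ATF4 response may be the reason. ATF4 targets other than these had a median of 0.19 (0.12 to 0.23) in cTEC, 21 of 27 above 0. Among them, Asns stood at 0.72 and Slc7a11 at −0.21 (−0.34 to −0.08). Without Asns, Chac1, Ddit3 and Slc7a11, which also stand in lists written before, the median was 0.20 (0.13 to 0.23, percentile 100), 19 of 24 above 0, with Atf5 at 0.95 (778 and 1724 reads) and Slc7a5 at 0.61. In mTEC the medians were 0.01 and 0.0008 (percentiles 64.4 and 49.3), with a sign that depends on the scaling, and the difference between populations was not tested.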
